A study of Mus musculus with 6 samples.

How the data were processed

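Circular RNAs (circRNAs), RNA molecules closed by a back-splice junction that joins a downstream splice site to an upstream one, were measured by RNA sequencing in mouse brown preadipocytes at days 0, 4 and 8 of adipogenic differentiation, with 2 libraries per day. Per the labels' protocols, stromal vascular cells of C57BL/6 mice were cultured to near confluence, kept for 4 days in a medium with insulin, dexamethasone and isobutylmethylxanthine, and then for 4 days in a medium with insulin and the thyroid hormone T3. Total RNA was depleted of ribosomal and linear RNA before library construction, per the labels' protocols. The labels call the tissue of origin an inguinal brown depot. Whether the cells were brown was not tested here, since host genes were not analysed. They do not say whether the 2 replicates of a day came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

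Per the submitters' processing notes, FastQC 0.11.9 and HISAT2 2.2.0 were used and the genome build was mm9. The program that called the circRNAs is not given in the sources used here. The deposited table lists 3869 circRNAs by chromosome, start, end and strand. Some have an identifier of circBase, a public catalogue of circRNAs. It gives 1 CPM column per library, deposited by the authors as normalized values. Each column sums to 1e+06 over the listed circRNAs. All 3869 listed circRNAs were above 0 in both libraries of at least 1 day, so the table holds a selection by detection. This selection is not described in the labels and was found from the values. A circRNA seen by chance in both libraries of 1 day is listed, and one seen in a single library of each day is not. This inflates differences between days of circRNAs with few reads.

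Within a library every CPM value was a whole multiple of 1 step, with a largest deviation of 2.52e-07 of a step. The smallest non-zero value was 2 steps and no value was 1 step. A step was taken as 1 read, and the read numbers below are inferred in this way. The totals came to 43098 and 41299 reads at day 0, 45733 and 40384 reads at day 4, and 40819 and 42215 reads at day 8. In CPM, 1 read was worth 21.9 to 24.8 CPM. These are the reads of the listed circRNAs, not the sequencing depth, which is unknown. An entry of 0 means that the circRNA was listed at 0 and may have had 1 read.

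The choices of groups, tests and alternatives were made before the data were examined, apart from those named here as chosen later. The plan was written first for read counts, with a limma analysis for normalized values. Because the deposited values are CPM and the inferred reads start at 2, the limma analysis was used and no count model was run. The 3 days were fitted together with limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(CPM + 43.7), where the pseudocount of 43.7 CPM is the smallest non-zero value of the table. Fold changes are on this scale, which understates the change of circRNAs near the pseudocount. All 3869 circRNAs were tested, since the planned filter (above 0 in at least 2 libraries) removed none. The adjusted p is the Benjamini-Hochberg value over the circRNAs tested in a comparison, and "called" means an adjusted p under 0.05. The planned stricter filter of at least 10 reads in at least 2 libraries kept 1368 circRNAs, and its counts are given beside those of the whole table. With 2 libraries against 2, an exact two-sided permutation test cannot go below p = 0.333, and single values per library are given with their SD and without a test.

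Circular RNAs were named by a rule. The largest absolute log2 fold changes were taken among called circRNAs whose 2 libraries of one day lay above both of the other and whose mean CPM in the higher day was above 162, the median of the non-zero values. The table does not pair circRNAs with gene names, so the first 2 of each direction are given, with the 10 most abundant summarised. Coordinates are on mm9, from 1. The starts in the table count from 0. Against a GRCm38 annotation only 71 of the 3869 circRNAs (1.84%) had both ends on exon boundaries after adding 1 to the start, and 0 without it. No mm9 annotation was used here, so host genes, exons and the gene lists fixed beforehand were not analysed. In place of host genes, circRNAs that overlapped on the same strand were joined into 2511 loci and their CPM summed, a choice made after the data were seen. Of these loci, 1801 held 1 circRNA and the fullest held 17.

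The procedure was tested on simulated data. In 20 tables drawn from the means over all 6 libraries, with a dispersion of 0.0910 and 200 circRNAs changed in each, a mean of 3296 circRNAs passed the detection rule. For day 8 against day 0, among circRNAs with a mean of at least 10 reads, 8-fold changes were recovered in 38.5% of cases, 4-fold changes in 5.48% and 2-fold changes in 0%. Below 10 reads, 2.97% of 8-fold changes were recovered. Among unchanged circRNAs 1 of 44791 below 10 reads was called, and 0 of 17521 above. These simulations drew only listed circRNAs. In tables without change to which unlisted circRNAs were added in assumed numbers, the detection rule alone gave a mean of 86.5 to 375.9 calls for day 8 against day 0, so the rate below 10 reads does not hold for a table selected in this way.

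Spans of called circRNAs were compared by permutation tests with 1e+05 resamples, two-sided, and circBase listing by two-sided Fisher's exact tests. The alternatives covered the pseudocount, size factors by the median of ratios, no scaling, filters on reads, the replicate number as a block, fits of the 4 libraries of a pair of days, and leaving out each library in turn. Leaving out a library leaves 1 library in its day, and limma then assumes that this library varies like the others. The replicates of each day differed by more than counting noise (chi-square per degree of freedom 2.80 at day 0, 3.14 at day 4 and 2.35 at day 8). This does not tell separate cultures from repeat preparations of 1 sample, and each library was counted as 1 sample.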

Results

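Circular RNA profiles were obtained from mouse preadipocytes that the labels call brown. They were taken before induction (day 0), at the end of the induction phase (day 4) and at the end of the maturation phase (day 8), with 2 libraries per day. Brown adipocytes burn lipid to make heat, and they form from such precursors in culture within days. The table listed 3869 circRNAs, of which 2442 (63.1%) carried a circBase identifier. The libraries held between 40384 and 45733 inferred back-splice reads on these circRNAs, and 1248 circRNAs were above 0 in all 6 libraries. The median genomic distance between the joined ends was 7871 bp, with a range of 142 to 191363 bp. Across circRNAs, which are not independent replicates, Spearman's rho of libraries of the same day was 0.667 at day 0, 0.667 at day 4 and 0.696 at day 8. Between days it lay between 0.440 and 0.563. The first 2 principal components held 34.4% and 26.8% of the variance, and the libraries of each day lay next to each other on both. The selection of the table by detection in both libraries of a day favours such agreement within days. Neither result can therefore tell a change between days from this selection.

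More circRNAs were above 0 at day 8 than earlier. Their number was 2782 ± 100 (SD, n = 2) at day 0, 2748 ± 122 at day 4 and 2996 ± 38.9 at day 8, and both day 8 libraries (2968 and 3023) lay above the highest earlier library (2853). The number with at least 5 reads did not follow this order, with 1979 ± 40.3 at day 0, 1883 ± 84.9 at day 4 and 1937 ± 21.2 at day 8. The share of CPM on circBase-listed circRNAs was 82.6% ± 0.303 at day 0, 82.7% ± 0.114 at day 4 and 80.3% ± 0.0159 at day 8 (SD, n = 2). No p-value under 0.333 can be reached by an exact permutation test on 2 against 2 libraries. In the table, 154 circRNAs were listed at day 0 alone, 122 at day 4 alone and 212 at day 8 alone, with median totals of 8, 7 and 7 reads.

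The most abundant circRNAs were present throughout. The circRNA mmu_circ_0001052 (chromosome 2, 104310906 to 104312004, minus strand) had 12820 ± 49.2 CPM at day 0, 15204 ± 2031 at day 4 and 11707 ± 965 at day 8 (SD, n = 2), and was called in no comparison (adjusted p = 0.262 to 0.666). Of the 10 with the highest mean, 8 were called in no comparison. The exceptions were chosen after their values were seen. One was mmu_circ_0011707 (chromosome 4, 58188803 to 58192579, minus strand), which rose from 7740 ± 183 CPM at day 0 to 13770 ± 38.5 at day 4 (log2 fold change 0.83, adjusted p = 0.0174). The other was mmu_circ_0001396 (chromosome 5, 119043342 to 119043579, plus strand), which rose from 6572 ± 533 CPM at day 0 to 13542 ± 424 at day 8 (log2 fold change 1.04, adjusted p = 0.0353). The circRNA mmu_circ_0011707 was not called when any of the 6 libraries was left out (adjusted p = 0.0976 to 0.277), nor in a fit of the 4 libraries of days 0 and 4 (0.0977). The circRNA mmu_circ_0001396 was not called without day 0 replicate 1 (0.303), day 0 replicate 2 (0.232), day 8 replicate 1 (0.297) or day 8 replicate 2 (0.269), nor without scaling (0.114) or with a pseudocount of 0.1 (0.0520).

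The comparison of day 4 with day 0 covers the induction phase. A circRNA on chromosome 9 (48525388 to 48641204, minus strand, no circBase identifier) was listed at 0 in both day 0 libraries and reached 678 ± 154 CPM (SD, n = 2; 36 and 23 reads) at day 4 (adjusted p = 0.00323). The circRNA mmu_circ_0000937 (chromosome 19, 17716983 to 17753047, minus strand) rose from 34.8 ± 49.2 CPM to 887 ± 111 CPM, a log2 fold change of 3.72 (SE 0.57, adjusted p = 0.0121). In the other direction, a circRNA on chromosome 9 (96618629 to 96632732, minus strand, no circBase identifier) fell from 1494 ± 78.6 CPM to 83.8 ± 56.6 CPM, a log2 fold change of -3.67 (SE 0.42, adjusted p = 0.00393). The circRNA mmu_circ_0001293 (chromosome 4, 141966372 to 141967259, minus strand) had 262 ± 74.9 CPM at day 0, was listed at 0 in both day 4 libraries (adjusted p = 0.0485) and had 241 ± 39.8 CPM at day 8. Among circRNAs with at least 10 reads in at least 2 libraries, the limma adjusted p was 0.0252 for both circRNAs on chromosome 9. It was 0.0287 for mmu_circ_0000937 and 0.0486 for mmu_circ_0001293. These calls rested on few libraries and none held in a fit of the 4 libraries of days 0 and 4 alone (adjusted p = 0.0629 for both circRNAs on chromosome 9, 0.0850 for mmu_circ_0000937 and 0.0985 for mmu_circ_0001293). The first was not called without day 4 replicate 1 (0.0510), and mmu_circ_0000937 was not called without day 4 replicate 1 (0.122), day 4 replicate 2 (0.141), day 8 replicate 1 (0.0714) or day 8 replicate 2 (0.0738). The falling circRNA on chromosome 9 was not called without day 0 replicate 1 (0.0638) or day 0 replicate 2 (0.0658), and mmu_circ_0001293 was not called when any library was left out (0.0932 to 0.175). With pseudocounts of 1 and 0.1 neither mmu_circ_0000937 (0.146 and 0.236) nor mmu_circ_0001293 (0.0524 and 0.0602) was called.

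Between day 0 and day 4, limma called 314 of 3869 circRNAs, 149 higher and 165 lower at day 4. A fit of the 4 libraries of these days alone called 37, 21 higher and 16 lower, of which 23 were among the 314. The balance of directions also depended on single libraries, with 132 higher and 97 lower without day 4 replicate 1, 140 and 98 without day 4 replicate 2, and 97 and 132 without day 8 replicate 2. Of the 314, 262 had a mean under 10 reads and 269 were listed at 0 in both libraries of the other day, a pattern that the selection of the table favours. Among the 1368 circRNAs with at least 10 reads in at least 2 libraries, 50 were called, 31 higher and 19 lower. This smaller count depended on every library, and it was 0 (limma, 256 at an unadjusted p under 0.05) in a fit of the 4 libraries alone. It was 15 without day 0 replicate 1, 4 without day 0 replicate 2 and 1 without day 4 replicate 1. It was 0 (limma) without day 4 replicate 2, day 8 replicate 1 or day 8 replicate 2, where 247, 249 and 255 circRNAs were at an unadjusted p under 0.05.

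**Figure D1:**
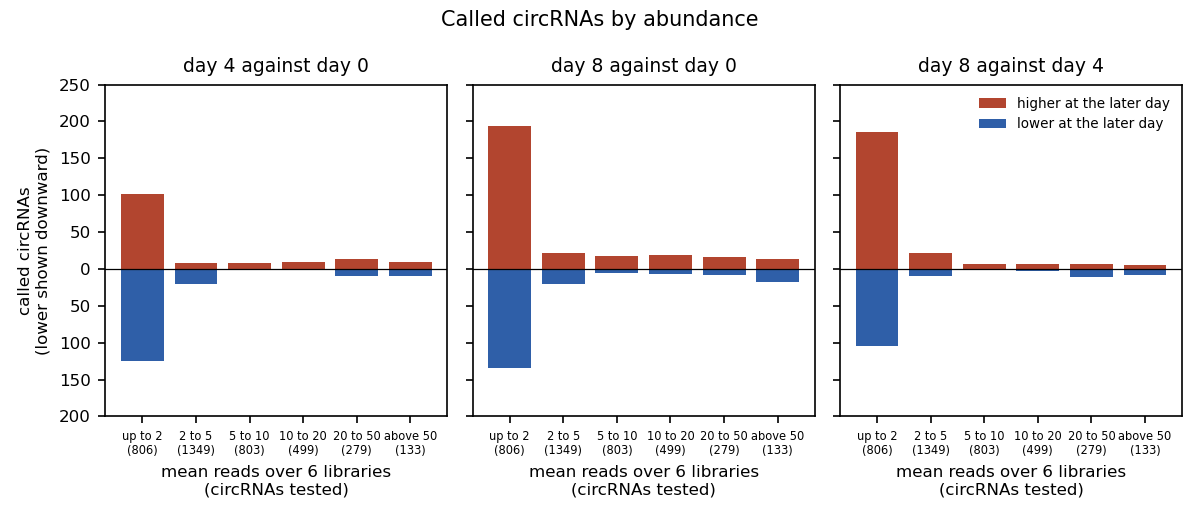
Number of called circRNAs (limma, adjusted p under 0.05; higher upward, lower downward) in 3 comparisons, by the mean number of inferred reads over the 6 libraries, with the number tested in each class below. The class of up to 2 reads holds 806 circRNAs and most calls, with 194 higher and 134 lower for day 8 against day 0.

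The comparison of day 8 with day 0 covers the whole course. A circRNA on chromosome 10 (106482269 to 106490572, minus strand, no circBase identifier) was listed at 0 at day 0 and had 240 ± 93.9 CPM at day 4 (SD, n = 2). At day 8 it had 2428 ± 654 CPM from 118 and 83 reads (adjusted p = 0.00092 against day 0). A circRNA on chromosome 3 (94743568 to 94744148, plus strand, no circBase identifier) was also listed at 0 at day 0 and reached 1470 ± 69.0 CPM (62 and 60 reads) at day 8 (adjusted p = 0.00362). Another on chromosome 3 (141966907 to 141977412, minus strand, no circBase identifier) had 918 ± 408 CPM at day 0 and 993 ± 136 CPM at day 4 and was listed at 0 in both day 8 libraries (adjusted p = 0.00172 against day 0). A circRNA on chromosome 6 (91200852 to 91207820, plus strand, no circBase identifier) went from 510.5 ± 65.7 CPM through 79.4 ± 42.3 CPM to 0 (adjusted p = 0.0163). Among circRNAs with at least 10 reads in at least 2 libraries, the limma adjusted p was 0.00388 for the circRNA on chromosome 10. It was 0.0104 for the rising and 0.00598 for the falling one on chromosome 3, and 0.0178 for that on chromosome 6. The calls of the circRNA on chromosome 10 and of the falling one on chromosome 3 held with any library left out (highest adjusted p 0.0188 and 0.0248). The rising circRNA on chromosome 3 was not called without day 0 replicate 1 (0.0548), day 0 replicate 2 (0.0521), day 8 replicate 1 (0.0995) or day 8 replicate 2 (0.0964). The circRNA on chromosome 6 was not called without day 0 replicate 1 (0.0766), day 0 replicate 2 (0.0812), day 8 replicate 1 (0.0675) or day 8 replicate 2 (0.0681).

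**Figure D2:**
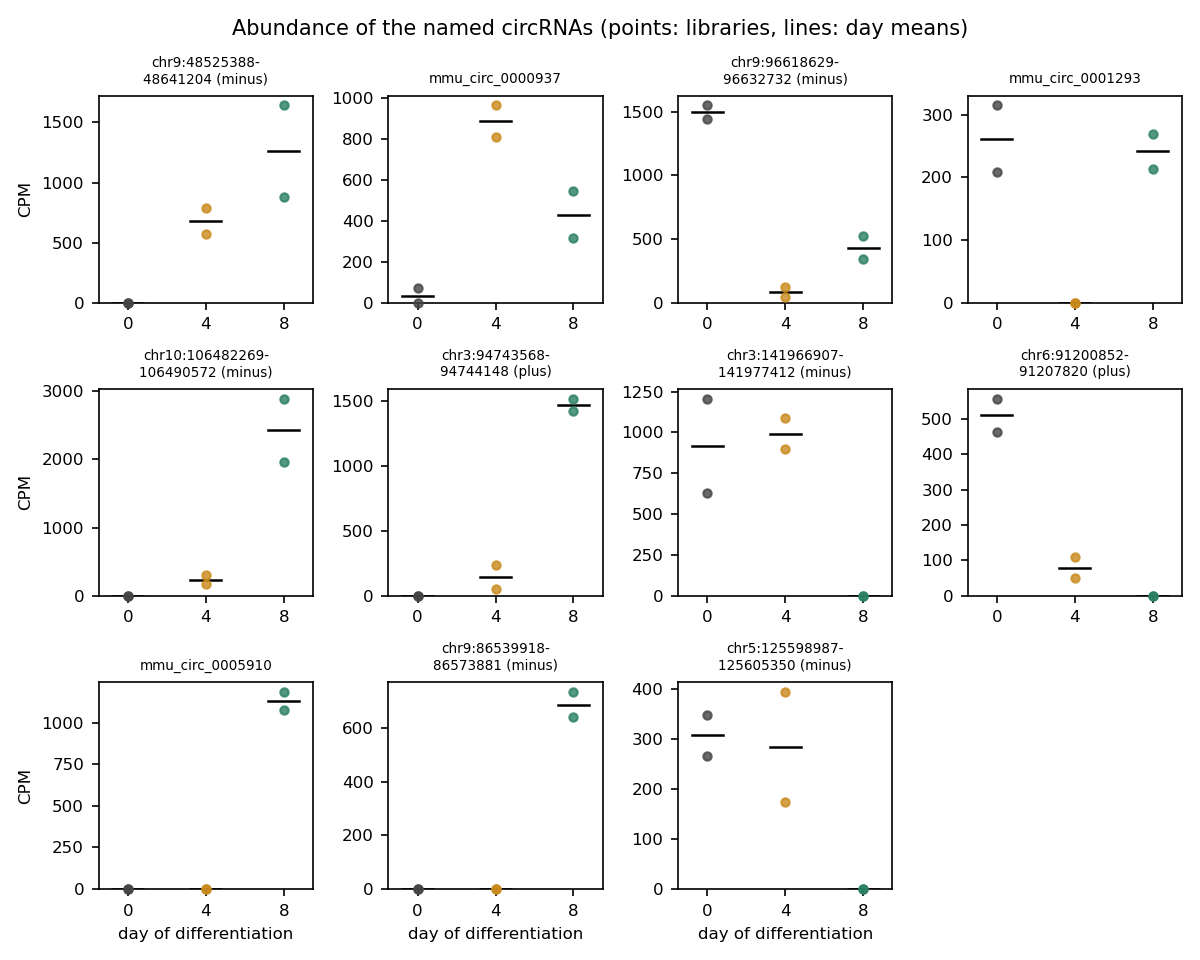
CPM of each named circRNA by day of differentiation (points, the 2 libraries of a day; lines, day means; linear axes from 0, scaled per panel). The circRNA on chromosome 10 goes from 0 at day 0 to 240 CPM at day 4 and 2428 CPM at day 8, and the one on chromosome 3 (141966907 to 141977412) is at 0 in both day 8 libraries.

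For day 8 against day 0, limma called 477 circRNAs, 283 higher and 194 lower at day 8, of which 393 had a mean under 10 reads and 405 were listed at 0 in both libraries of the other day. The 194 lower became 129 without day 8 replicate 1 and 121 without day 8 replicate 2. With at least 10 reads in at least 2 libraries, 92 of 1368 were called, 59 higher and 33 lower, and 90 of them were called in the whole table too. Of the 92, 37 were listed at 0 in both libraries of the other day. The count was 20 without day 0 replicate 1, 23 without day 0 replicate 2, 13 without day 8 replicate 1 and 9 without day 8 replicate 2, against 82 and 80 without either day 4 library.

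Several changed circRNAs overlapped one another. On chromosome 10 (106460710 to 106522007, minus strand) 5 overlapping circRNAs were all listed at 0 at day 0 and summed to 493 ± 137 CPM at day 4 and 4670 ± 775 CPM at day 8 (SD, n = 2). The adjusted p of the sum at day 8 against day 0 was 0.00175, and all 5 were called higher at day 8 than at day 0. On chromosome 15 (3275898 to 3501685, minus strand) 7 of 13 overlapping circRNAs were called higher at day 8, and their sum rose from 359 ± 212 CPM at day 0 to 2551 ± 212 CPM at day 8 (log2 fold change 2.79, SE 0.40, adjusted p = 0.00771). On chromosome 6 (118952595 to 119019207, minus strand) the sum of 7 circRNAs fell from 15443 ± 1294 CPM to 4683 ± 861 CPM (log2 fold change -1.72, SE 0.23, adjusted p = 0.0056), with 3 of the 7 called lower. On chromosome 7 (117170585 to 117180614, plus strand) 3 of 3 circRNAs were called lower and the sum fell from 2516 ± 277 CPM to 1011 ± 78.2 CPM (log2 fold change -1.28, SE 0.17, adjusted p = 0.00534). With at least 10 reads in at least 2 libraries, 4 circRNAs of the locus on chromosome 10, 1 on chromosome 15, 3 on chromosome 6 and 1 on chromosome 7 were called. These 4 are among 10 loci with at least 3 circRNAs called in one direction at day 8 against day 0, a rule set after the data were seen. The sum on chromosome 15 was not called without day 8 replicate 1 (0.107) or day 8 replicate 2 (0.117), and that on chromosome 6 was not called without day 0 replicate 1 (0.106), day 0 replicate 2 (0.0810), day 8 replicate 1 (0.0682) or day 8 replicate 2 (0.107).

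The other loci with at least 3 called circRNAs moved in both directions. The sums of 3 of them were called for day 8 against day 0 with any library left out. They rose from 404 ± 45.7 to 3275 ± 24.3 CPM on chromosome 16 (70401979 to 70495644, plus strand, adjusted p = 0.00175), from 1515 ± 88.4 to 7648 ± 1067 CPM on chromosome 9 (83845890 to 83962798, plus strand, 0.00175) and from a listed 0 to 1838 ± 623 CPM elsewhere on chromosome 9 (48525388 to 48641204, minus strand, 0.00175). The other 3 sums were less stable. On chromosome 7 (94444294 to 94524792, plus strand) the sum rose from 156 ± 156 to 3024 ± 123 CPM (adjusted p = 0.0220), but was not called without day 0 replicate 1 (0.159), day 0 replicate 2 (0.0645), day 8 replicate 1 (0.212) or day 8 replicate 2 (0.205), without scaling (0.0545) or with pseudocounts of 1 (0.0646) and 0.1 (0.0725). On chromosome 19 (37119012 to 37213711, minus strand) it rose from 24.2 ± 34.2 to 663 ± 32.8 CPM (0.0313), but was not called with those pseudocounts (0.147 and 0.214), nor without day 0 replicate 1 (0.123), day 0 replicate 2 (0.0707), day 4 replicate 2 (0.0540), day 8 replicate 1 (0.206) or day 8 replicate 2 (0.193). On chromosome 14 (47529786 to 47672788, plus strand) it fell from 5139 ± 1035 to 1613 ± 29.8 CPM (0.0140), but was not called without day 0 replicate 1 (0.138), day 0 replicate 2 (0.0809), day 8 replicate 1 (0.158) or day 8 replicate 2 (0.153). With at least 10 reads in at least 2 libraries, 2 circRNAs of each locus on chromosome 9, 2 on chromosome 7, 1 on chromosome 16 and 1 on chromosome 14 were called, and none on chromosome 19.

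Some loci held calls in both directions, 7 for day 4 against day 0, 4 for day 8 against day 0 and 3 for day 8 against day 4, and none did with at least 10 reads in at least 2 libraries. For day 8 against day 0, a circRNA on chromosome 6 (91202438 to 91204615, plus strand) inside the named falling one went from 0 to 71.9 ± 32.4 CPM (2 and 4 reads at day 8, adjusted p = 0.00661). The others lay on chromosome 8 (88366903 to 88425856 lower, 88464740 to 88494896 and 88372573 to 88494896 higher), chromosome 12 (13397731 to 13415113 lower, 13381502 to 13422537 higher) and chromosome X (12321843 to 12333581 lower, 12322872 to 12326463 higher), with at most 7 reads in any library. For day 8 against day 4 they lay on chromosome 1 (5085696 to 5114550 lower, 5085696 to 5091204 higher), chromosome 6 (98965418 to 99026039 and 98965418 to 99113023 lower, 98953194 to 98960048 higher) and chromosome 9 (31977675 to 32015850 lower, 31977675 to 31997646 higher), also with at most 7 reads.

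Over all 2511 loci, 339 sums were called, 198 higher and 141 lower at day 8 than at day 0 (219 without day 8 replicate 2, and 146 higher and 84 lower without day 8 replicate 1), and 115 of the 1140 sums with at least 10 reads in at least 2 libraries were called.

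**Figure D3:**
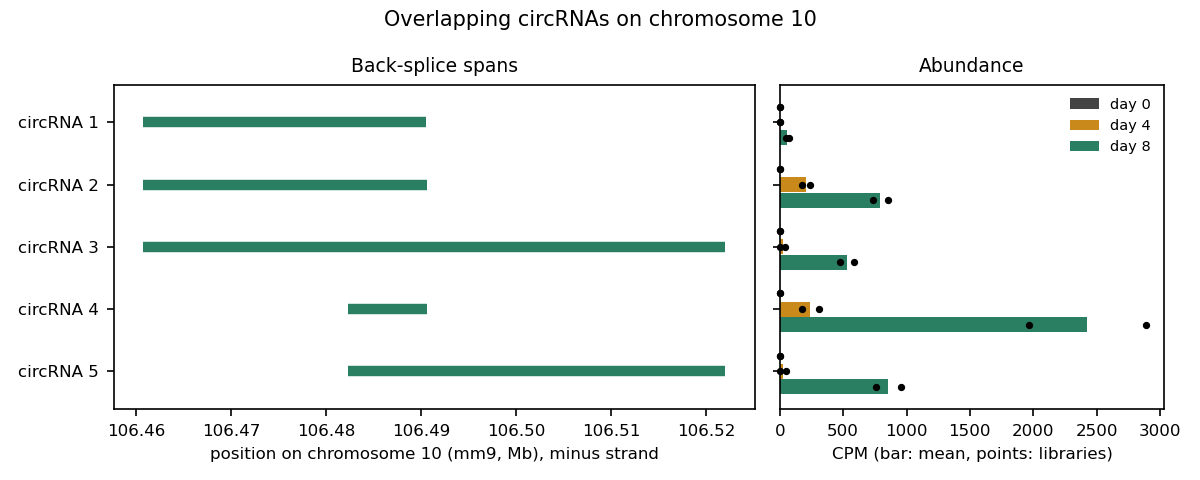
Back-splice spans of the 5 overlapping circRNAs on chromosome 10 (left, position on mm9 in Mb, minus strand) and their CPM at days 0, 4 and 8 (right; bars, means; points, libraries). None was above 0 at day 0, and their sum was 4670 CPM at day 8.

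The comparison of day 8 with day 4 covers the maturation phase. The circRNA mmu_circ_0005910 (chromosome 15, 84001512 to 84016511, plus strand) was listed at 0 in all 4 libraries of days 0 and 4 and had 1131 ± 75.3 CPM (SD, n = 2; 44 and 50 reads) at day 8 (adjusted p = 0.00565). A circRNA on chromosome 9 (86539918 to 86573881, minus strand, no circBase identifier) was likewise listed at 0 at days 0 and 4 and had 687 ± 67.4 CPM at day 8 (adjusted p = 0.00989). The circRNA on chromosome 3 (141966907 to 141977412) was listed at 0 at day 8 after 993 ± 136 CPM at day 4 (adjusted p = 0.00154), and one on chromosome 5 (125598987 to 125605350, minus strand, no circBase identifier) after 283 ± 156 CPM (adjusted p = 0.0478). Within the filter of at least 10 reads in at least 2 libraries, the limma adjusted p was 0.0324 for mmu_circ_0005910. It was 0.0393 for the circRNA on chromosome 9 and 0.0324 for that on chromosome 3. The circRNA on chromosome 9 was not called without day 4 replicate 1 (0.0534) or day 4 replicate 2 (0.0560). That on chromosome 5 was not called when any library was left out (0.0736 to 0.177), nor among circRNAs with at least 10 reads in at least 2 libraries (0.0901). It was also not called with median-of-ratios size factors (0.0501), without scaling (0.0595) or in a fit of the 4 libraries of days 4 and 8 (0.0917).

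Between day 4 and day 8, limma called 370 circRNAs, 233 higher and 137 lower at day 8, of which 329 had a mean under 10 reads. The 137 lower became 85 without day 8 replicate 1. With at least 10 reads in at least 2 libraries, 14 were called, 10 higher and 4 lower, against 4 in a fit of the 4 libraries of these days, 9 with a pseudocount of 1 and 7 with one of 0.1. That count was 1 without day 4 replicate 1, 5 without day 8 replicate 1 and 6 without day 8 replicate 2. It was 0 (limma) without day 0 replicate 1, day 0 replicate 2 or day 4 replicate 2, where 222, 217 and 183 circRNAs were at an unadjusted p under 0.05.

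Over the 3 days together, 571 circRNAs were called in the whole table, of which 481 had a mean under 10 reads. With at least 10 reads in at least 2 libraries, 82 of the 1368 were called. By the order of the day means alone, without a test of each step, 31 of these 82 went up at both steps, 16 went down at both, 23 were highest at day 4 and 12 lowest at day 4. The count of 82 was 16 without day 0 replicate 1, 14 without day 0 replicate 2, and 46 without day 4 replicate 2. No circRNA was called by limma without day 8 replicate 1 or day 8 replicate 2, where 245 and 263 were at an unadjusted p under 0.05.

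The calls of day 4 and of day 8 against day 0 overlapped. In the whole table, 26 circRNAs were higher at both days and 151 lower at both, where independent lists would share 10.9 and 8.27, and 0 were called in opposite directions. The table lists 154 circRNAs at day 0 alone, which are at 0 at both later days. Such circRNAs can be lower at both days through the selection of the table, so the 151 cannot be judged against 8.27. With at least 10 reads in at least 2 libraries, 21 were higher and 8 lower at both days, against 1.34 and 0.458. In tables simulated without change, limma called 0 circRNAs in either comparison, so the 0 shared calls there say nothing about overlap through shared day 0 libraries. Where circRNAs left out of the table were simulated as well, a mean of 43.1 to 186 calls were shared in the whole table. With at least 10 reads in at least 2 libraries 0 were shared there, but next to no circRNAs were called. The log2 fold changes correlated at r = 0.581 across circRNAs, with a covariance of 0.771. The simulated groups gave r = 0.50 and a covariance of 0.224. Both comparisons used the same 2 day 0 libraries, so part of the excess of shared calls over independent lists may come from these. The simulated r and covariance already include such sharing. Those tables drew only listed circRNAs, so they do not hold the full selection of the table, and the higher observed values cannot be told apart from it. The 177 shared calls of the whole table became 94 without day 4 replicate 1, 100 without day 4 replicate 2 and 117 without day 8 replicate 2. The 29 with at least 10 reads in at least 2 libraries became 10 without day 0 replicate 1, 3 without day 0 replicate 2, and 0 without any one of the 4 libraries of days 4 and 8.

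Circular RNAs that were higher at day 8 than at day 0 spanned more of the genome than those that were lower. In the whole table the median spans were 8934 bp for the 283 higher and 5169 bp for the 194 lower circRNAs, a difference of 3765 bp (permutation test, two-sided p = 0.00131, adjusted p = 0.00605 over 16 tests). Without day 8 replicate 2 the difference was 1694 bp (permutation p = 0.258). Among called circRNAs with at least 10 reads in at least 2 libraries, the medians were 19205 bp for 59 higher and 3817 bp for 33 lower circRNAs (permutation test, p = 0.00433, adjusted p = 0.00866). The test was not repeated without single libraries in this set, where leaving out any day 0 or day 8 library left 8 to 19 higher and 1 to 5 lower calls. At day 4 against day 0 the medians of the whole table were 18536 bp for the higher and 4915 bp for the lower circRNAs (permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 0.00016). This is not an independent result, since both comparisons used the same day 0 libraries. Of the 165 circRNAs lower at day 4, 151 were also lower at day 8. Among circRNAs with any change over the 3 days, split by their direction at day 8 against day 0, the difference of 2169 bp did not pass the threshold (permutation p = 0.0539, adjusted p = 0.0958). The median number of circRNAs in the same locus lay between 1 and 2 in every set, too coarse a measure for this test. Circular RNAs are not independent replicates in these tests.

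**Figure D4:**
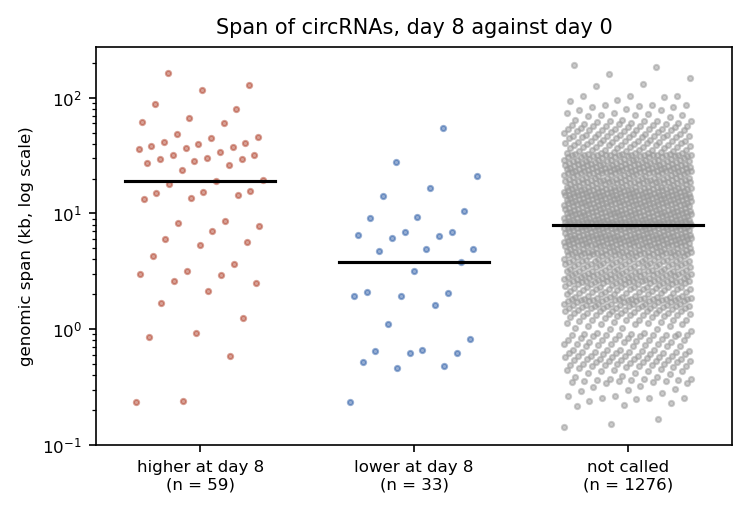
Genomic span (kb, log scale) of circRNAs with at least 10 reads in at least 2 libraries, by their call for day 8 against day 0 (points, circRNAs; lines, medians). The 59 higher circRNAs have a median of 19205 bp and the 33 lower ones of 3817 bp.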

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

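The counts of called circRNAs moved with the read filter, the libraries fitted and, within the read filter, single libraries. Chosen after seeing the data were the filter on mean reads, the locus sums, the span tests on subsets and without single libraries, and the repeat of every setting within the circRNAs with at least 10 reads in at least 2 libraries. With that read filter the counts were 50 for day 4 against day 0, 92 for day 8 against day 0, 14 for day 8 against day 4 and 82 over the 3 days, and with a mean of at least 10 reads 42, 78, 9 and 67. For locus sums the same 2 filters gave 63, 115, 24 and 126, and 72, 110, 34 and 121. Fits of the 4 libraries of days 0 and 4 gave 37 circRNAs and 115 loci. With at least 5 reads the circRNAs per library numbered 1978.5 at day 0, 1883 at day 4 and 1937 at day 8, and the read filter left 29 shared calls of days 4 and 8 (0 to 10 when single libraries were left out). In the set of circRNAs with any change the span difference was 2169 bp (adjusted p = 0.0958). Beyond fewer circRNAs tested and fewer samples, the cause was not tested.

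Leaving out single libraries gave 229 to 287, 356 to 451, 306 to 362 and 470 to 540 called circRNAs for day 4 against day 0, day 8 against day 0, day 8 against day 4 and the 3 days, and 145 to 169, 219 to 347, 157 to 261 and 302 to 355 loci. For day 8 against day 4, 157 loci were called without day 4 replicate 1 and without day 4 replicate 2, against 248. Within the read filter the ranges were 0 to 15, 9 to 82, 0 to 6 and 0 to 56. Fewer residual degrees of freedom may be part of this. Either day 8 library enters day 4 against day 0 only through the shared spread, yet leaving it out also removed the filtered calls of that comparison. Leaving out either day 4 library, however, lowered the filtered calls of day 8 against day 0 far less. The cause was not tested. The shared calls ranged from 94 to 185, the span difference from 1694 to 4542 bp, and the circRNAs per library from 2711 to 2853 at day 0, 2661 to 2834 at day 4 and 2968 to 3023 at day 8. Within the read filter, fits of 4 libraries gave 0 calls in limma for day 4 against day 0 (256 at an unadjusted p under 0.05) and 4 for day 8 against day 4, for which pseudocounts of 1 and 0.1 gave 9 and 7.

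No pairing by replicate number was seen, as the deviations of same-numbered libraries correlated at -0.0136, -0.00671 and -0.00705 between days. This was taken over all 3869 circRNAs, of which 923 had a mean of at least 10 reads. Counting noise in the others pulls such correlations towards 0, so pairing cannot be excluded. With the replicate number as a block the counts were 309, 460, 355 and 558. Within the read filter they were 11, 48, 0 and 18, with 5 shared calls of days 4 and 8. The count of 0 was that of day 8 against day 4 (limma, 203 at an unadjusted p under 0.05). Of the circRNAs named, mmu_circ_0001293 (adjusted p = 0.10) and mmu_circ_0011707 (0.0504) for day 4 against day 0, and the one on chromosome 5 (125598987 to 125605350, 0.0788) for day 8 against day 4, were not called with the block.

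Of the values of single circRNAs and loci, 547 kept direction and side of the threshold, 128 fell short of it, 4 passed it and 7 changed sign, none of them called. The sum on chromosome 15 (3275898 to 3501685) for day 4 against day 0 was -0.449 (log2) without day 0 replicate 1 and -0.0067 without day 4 replicate 2, with a highest value of 0.679 when other libraries were left out. That on chromosome 7 (94444294 to 94524792) was -0.486 without day 0 replicate 1 and -0.502 without day 4 replicate 1, with a highest value of 1.31. That on chromosome 14 (47529786 to 47672788) for day 8 against day 4 was -0.0381 without scaling, -0.341 without day 4 replicate 1 and -0.00831 without day 8 replicate 2, with a highest value of 0.361. The cause was not tested. Having no filter and a minimum of 2 reads removed no circRNA, and library totals are already the scale of CPM, so these settings tested nothing. Count models, host gene sums and gene lists were not run.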

Other observations

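Tests on the read filter of the table for circRNAs of low and of high abundance were chosen after the result was seen. So were those on the totals of listed reads and on loci with many circRNAs, and the circBase comparisons. Among circRNAs with at least 10 reads in at least 2 libraries, those higher at day 8 than at day 0 were less often listed in circBase. Without an identifier were 25 of 59 (42.4%) of them and 242 of the 1309 others (18.5%; Fisher's exact test, two-sided p = 3.42e-05, adjusted p = 0.000205 over 6 tests). With strata of abundance the exact p was 1.32e-05. Circular RNAs are not independent replicates here either. The 59 higher ones lay in 51 loci, and circBase listing was not tested with 1 circRNA per locus. Of the 10 higher at day 8 than at day 4, 7 had none (70%, adjusted p = 0.00211), and of the 31 higher at day 4 than at day 0, 10 had none (32.3%, adjusted p = 0.208). Among the 33 lower at day 8 than at day 0 the share was 18.2% (adjusted p = 1). The 92 calls between day 8 and day 0 behind these shares fell to between 9 and 23 when any library of those days was left out. The 14 calls between day 8 and day 4 fell to between 0 and 6 when any library was left out, with 0 (limma, 222, 217 and 183 at an unadjusted p under 0.05) without day 0 replicate 1, day 0 replicate 2 or day 4 replicate 2. The 50 between day 4 and day 0 fell to between 0 and 15.

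The calls between day 8 and day 0 may be partly a product of how the table was selected. For circRNAs with a mean of at least 10 reads, which such a selection hardly touches, 24.8% (exact 95% interval 22.1 to 27.7) were at an unadjusted p under 0.05 and 5.02% in simulated tables without change, which argues against selection as the whole cause there. The interval treats circRNAs as independent, which they are not, so it does not measure the spread between samples. For scaling, 90 of the 92 filtered calls were kept with median-of-ratios size factors. These factors (0.932 to 1.10) lay close to the library totals divided by their mean (0.956 to 1.08), so the calls could hardly change. Both scales rest on the listed circRNAs, so a change in total circRNA content was not tested. For circRNAs with fewer reads selection cannot be told apart from change in the whole table, because the number left out of it is unknown. Unchanged tables simulated with 20000 further circRNAs at a mean of 0.5 reads gave 283.6 calls, and the other settings 86.5 to 375.9. With at least 10 reads in at least 2 libraries these tables gave a mean of 0 to 0.1 calls, against 92. The circRNAs added there were drawn around an assumed mean of 0.5 or 1 read, so few could reach this filter. These tables therefore cannot tell whether selection adds to the filtered calls. Of the 92, 37 were listed at 0 in both libraries of the other day. Differentiation stays open as the biological explanation for the abundant circRNAs.

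The larger number of circRNAs above 0 at day 8 was not explained by the totals of listed reads. After thinning every library to 40384 such reads, the lowest day 8 library still lay 119.2 circRNAs above the highest other library. The totals at day 8 (40819 and 42215 reads) already lay within the range of the earlier ones (40384 to 45733). Sequencing depth is unknown and was not tested. A candidate explanation is that the selection favours the day whose libraries are most alike. Over circRNAs listed through the other days, the lowest day 8 library lay -127 circRNAs from the highest other one, but the sets differ in size (3322, 3434 and 3173 for days 0, 4 and 8). As shares of these sets, the day 8 libraries had 71.6% and 73.3%, and the others 64.8% to 69.9%, so that this selection and a broader circRNA population cannot be told apart.

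The longer spans of circRNAs higher than at day 0 were seen at day 8 and, with a larger difference in the whole table (13621 against 3765 bp), at day 4. The 2 comparisons are not independent, since they share the day 0 libraries. Of the 165 circRNAs lower at day 4, 151 were also lower at day 8, and the selection of the table favours such calls. No biological explanation was tested. A few loci with many circRNAs are argued against as the whole cause with all 6 libraries, since among called circRNAs with at least 10 reads in at least 2 libraries, where the median difference was 15388 bp, it was 12379 bp with 1 circRNA per locus (permutation test, adjusted p = 0.00605). Misassigned long-range junctions absent from circBase are argued against in the same way, with 14610 bp among the circBase-listed ones of that filtered set (adjusted p = 0.00605), and neither test was run on the whole table. The difference in the whole table was 1694 bp without day 8 replicate 2 (permutation test, p = 0.258), and among circRNAs with any change over the 3 days it was 2169 bp (adjusted p = 0.0958), so the pattern rests in part on that library and on the set chosen, and the filtered calls fell to 8 to 19 higher and 1 to 5 lower when any day 0 or day 8 library was left out.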
